A study of Homo sapiens with 6 samples.

How the data were processed

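The material was the human glioblastoma cell line U251, in 2 stable versions: cells that carried an empty vector (pEV) and cells that expressed microRNA-203 from a vector (pmiR-203). Each version was measured in 3 libraries, described in the labels' protocols as biological triplicates. Total RNA was extracted with a column kit and treated with DNase, and strand-specific libraries were made with dUTP in the second cDNA strand, per the labels' protocols. The labels do not say whether mRNA was selected or ribosomal RNA removed. Each group is 1 stable line, so the p-values measure the spread between libraries of 1 line and not between independently made lines.

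The deposited tables hold FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), per the file headers, at the level of genes and of transcripts. The submitters' processing notes list cutadapt, HISAT2 and StringTie and the builds hg19 and GRCh37, without order, role or version. The gene and transcript coordinates are those of hg19. The annotation release is not given in the sources used here. The gene table has 12610 rows and the transcript table has 31187 rows. All rows are of the type protein coding, and in each row the larger of the 2 group means was at least 0.5 FPKM, which was tested on the values. That filter removes genes low in both groups before any test. Replicates were not pooled.

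FPKM values are not counts, so no count model was fitted and the planned count alternatives were not applicable. Depth was estimated from the step that 1 fragment makes in the FPKM of genes with 1 transcript row, with transcript lengths from GENCODE 29 and a tolerance of 1%. The estimates were 17200000, 20900000 and 11600000 mapped fragments for pEV 1, 2 and 3, and 25900000, 25200000 and 24900000 for pmiR-203 1, 2 and 3. The estimate for pEV 3 rested on 3 values at 1 fragment and is the least certain. The share of summed FPKM on mitochondrially encoded mRNAs was 8.0%, 9.8% and 10.9% in pEV and 11.1%, 10.9% and 10.9% in pmiR-203.

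Values were put on the scale log2(FPKM + 1), which understates the change of low genes. Genes and transcripts with a mean of at least 0.5 FPKM over the 6 libraries were tested, which left 12287 genes and 28450 transcripts. The test was the moderated test of limma 3.58.1 in R 4.3.3 with a mean-variance trend (two-sided), for pmiR-203 minus pEV without a replicate block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The authors' normalization was kept. Fold values printed beside FPKM are ratios of the group means of FPKM. They differ from the log2 fold changes, which are on the FPKM + 1 scale, and can differ widely for low genes. For SCUBE3 the ratio was 25.5, with a log2 fold change of 2.242.

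Of 31 gene lists written before the data were examined, 30 had at least 5 tested members and were compared with all other tested genes by camera in limma, with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Camera's direction is relative to the other genes, whose median log2 fold change was 0.09. Each list's calls are given over all genes tested and adjusted over the list alone.

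For the seed test, the longest annotated 3 prime UTR of each gene was taken from GENCODE 29, joined by gene ID for 12461 of the 12610 gene rows (98.8%). GENCODE 29 lies on a later build, so its coordinates were not used. Genes with a site for miR-203a-3p (8mer, 7mer-m8 or 7mer-A1) were compared with genes without one after regression on the logarithm of UTR length and on UTR GC share. The 7mer-m8 site was also ranked among 15923 heptamers found in at least 100 UTRs. Transcript GC shares came from the same release.

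Genes were named by a rule written before the data were examined. It took the 12 genes with the largest increase and the 12 with the largest decrease among genes past the threshold with a mean of at least 1 FPKM and no overlap between groups. It also took up to 4 members of each list by smallest p, or the 2 with the smallest p where fewer than 2 passed, every published miR-203 target past the threshold, and the 5 transcripts up and 5 down with the smallest p whose gene did not pass. Symbols of clones and of non-coding RNAs were not counted. Of the 12 decreased genes, 2 lie on the Y chromosome and are not reported. Some other genes that met the rule are not reported here. Overlap-free groups arise by chance in 10% of genes with 3 against 3 libraries. All rows are protein coding genes, and the level of the microRNA itself was not analysed here.

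The steps were tested on simulated libraries of 12287 genes for this comparison, with 200 genes changed. With a common spread, 32%, 62%, 82% and 84% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold were recovered, and 3% of the calls were false. With the spread that each group showed, 42%, 70%, 92% and 90% were recovered, and 17.9% of the calls were false, because the test assumes 1 spread for both groups. Noise was drawn independently for each gene, so shifts shared by many genes of a library were not simulated. The false shares also depend on how many genes were changed, so they do not carry over to the calls made in the data. In a simulated list test, the 1 shifted list was the only list called. A seed shift of -0.15, put into all genes with a site, was returned as -0.156, which checks the computation and not the sensitivity.

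Alternatives fixed before the data were examined were another pseudocount, other filters, median-of-ratios and quantile scaling, the replicate number as a block, each library left out in turn, other variance settings, a fold threshold of 1.5 and other definitions of the seed test. Alternatives added after the data were seen were a GC correction (a spline with 5 degrees of freedom on transcript GC, removed from each library), the same without pEV 3, pEV 2 alone against pmiR-203, and library weights. For pEV 2 alone, the lone control was assumed to vary like the pmiR-203 libraries, although the pEV libraries varied more (median SD 0.153 against 0.052). Gene families, tissue lists and chromosome stretches in the closing section were also chosen after the data were seen. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.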

Results

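The transcriptome of U251 cells, a human glioblastoma line, was profiled by strand-specific RNA sequencing to examine the processes that change with microRNA-203 (miR-203). Cells stably expressing miR-203 (pmiR-203, n = 3 libraries) were compared with cells carrying an empty vector (pEV, n = 3 libraries). Expression was given as FPKM for 12610 protein coding genes and 31187 transcripts. Estimated depth ran from 11600000 to 20900000 mapped fragments in pEV and from 24900000 to 25900000 in pmiR-203. The level of miR-203 itself was not analysed here, so the labels could not be checked against it.

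The 6 libraries were not equally alike within groups. Log2 values of the pmiR-203 libraries correlated across genes with a mean Pearson r of 0.989 for each library, and those of pEV 1, 2 and 3 with a mean r of 0.957, 0.966 and 0.953. The median within-group SD of log2 values was 0.153 in pEV and 0.052 in pmiR-203. In pEV 1, deviations from the gene means followed transcript GC share (Spearman rho = 0.557 across genes, which are not independent replicates), while rho lay between -0.266 and -0.119 in the other 5 libraries. In pEV 3, 99 genes lay more than 4-fold above each of the other libraries on the FPKM + 1 scale, against 4 such genes in pEV 1, 0 in pEV 2, and 3, 0 and 1 in pmiR-203 1, 2 and 3. Among the 99 were fat cell and blood genes: HBA1, a hemoglobin chain, stood at 482 FPKM in pEV 3 and at most 2.27 FPKM in the other 5 libraries. LEP, the fat cell hormone leptin, stood at 50.4 FPKM in pEV 3 and at most 0.320 FPKM elsewhere.

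**Figure D1:**
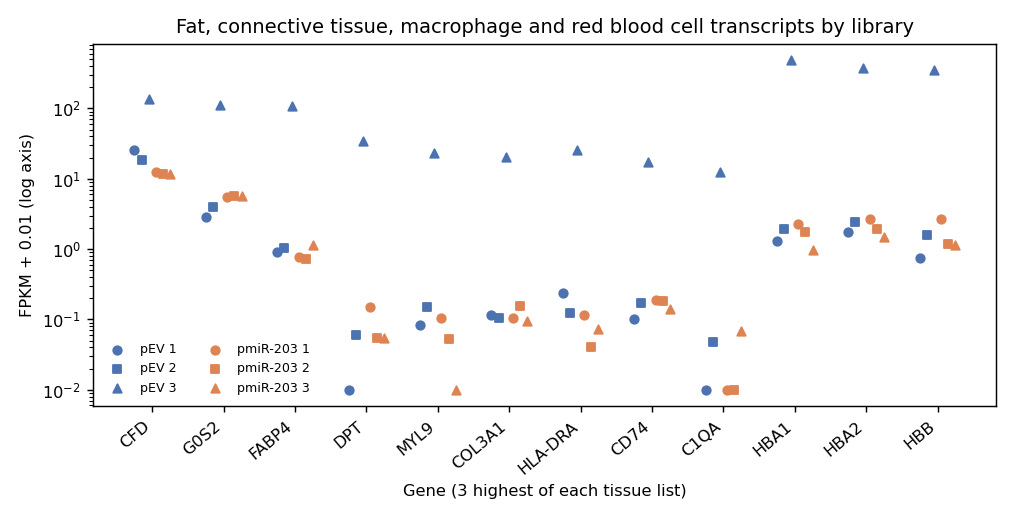
FPKM + 0.01 (log axis) of the 3 highest genes of each of 4 tissue lists in the 6 libraries, 1 point per library. The lists were written after the values were seen, and all 12 genes are highest in pEV 3, with HBA1 at 482 FPKM.

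The first question was which genes differed between the lines. KRT81, a hair keratin, rose from 14.6 ± 1.17 to 121 ± 0.596 FPKM (mean ± SD, n = 3 per group, 8.28-fold). The transcription factor E2F1, which drives entry into S phase, rose from 2.73 ± 0.114 to 8.51 ± 0.192 FPKM (3.12-fold). GFAP, the intermediate filament of astrocytes, rose from 19.0 ± 3.72 to 53.3 ± 0.479 FPKM (2.81-fold). HSPA5, the main chaperone of the endoplasmic reticulum, fell from 739 ± 53.6 to 342 ± 2.21 FPKM (2.16-fold lower).

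Of 12287 genes tested with limma, 3595 passed an adjusted p of 0.05, of which 2534 were higher and 1061 lower in pmiR-203. Most changes were small on the FPKM + 1 scale, which understates the change of low genes. On that scale, 1170 of the 3595 had a fold of at least 1.5 (828 higher, 342 lower). A fold of at least 2 was reached by 229 (162 higher, 67 lower). These counts do not use the ratios of FPKM means printed for single genes. The share of calls that were higher, 70.5%, was 52.2% (1745 higher, 1600 lower) after median-of-ratios scaling and 55.5% after quantile normalization, since the median log2 fold change of all genes moved from 0.09 to -0.01 and 0.01. The number of calls fell to 1710, 1746 and 1748 without pmiR-203 1, 2 and 3, and was 5409 without pEV 1, so single libraries moved it by over 1.5 times. Without pEV 3, 3312 genes passed.

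The 12 genes with the largest increases had log2 fold changes from 1.82 to 2.97. LY6E, a GPI-anchored surface protein, rose from 1.78 ± 0.771 to 19.2 ± 1.04 FPKM (10.8-fold). FAM20C, the kinase of the secretory pathway, rose from 12.3 ± 3.84 to 77.8 ± 0.459 FPKM. The cancer-testis antigens XAGE1E, XAGE1A and XAGE1D rose by 9.50-fold, 9.28-fold and 8.91-fold. These 3 genes are near-identical copies on chromosome X whose reads cannot be assigned with certainty, and they count as uncertain. SCUBE3 rose from 0.180 ± 0.0637 to 4.59 ± 0.422 FPKM and PCSK1N, an inhibitor of a prohormone convertase, from 0.480 ± 0.186 to 5.88 ± 0.119 FPKM. HAS2, a hyaluronan synthase, rose 4.93-fold, and CXCL14, a chemokine, rose from 25.3 ± 5.03 to 99.4 ± 2.91 FPKM. TSEN15, a subunit of the tRNA splicing endonuclease, rose 4.37-fold, and SIRPA, the receptor for CD47, rose 5.57-fold. Adjusted p-values from limma ran from 0.000106 for KRT81 to 0.00146 for SIRPA.

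Among the genes with the largest decreases, PAGE5, a further cancer-testis antigen, fell from 22.1 ± 5.84 to 4.70 ± 0.772 FPKM (4.71-fold lower). C22orf29 was 5.05-fold lower, EDN2 (endothelin 2) 3.90-fold lower, and the zinc finger gene ZNF791 4.66-fold lower. KLF2, a transcription factor induced by shear stress, fell from 16.1 ± 1.93 to 4.27 ± 0.119 FPKM. BCL2L11, which encodes the death-promoting protein BIM, fell from 8.12 ± 2.61 to 1.83 ± 0.672 FPKM, with an adjusted p of 0.00737 and of 0.0504 against pEV 2 alone. DIRAS3, a small GTPase, was 3.58-fold lower, PPL (periplakin) 3.08-fold, SFRP4, a secreted Wnt antagonist, 3.21-fold, and TIMP3, an inhibitor of metalloproteinases, 2.97-fold.

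KRT81 (ENSG00000205426.10_1) lies at chromosome 12, 52679697 to 52685318, E2F1 (ENSG00000101412.12_1) at chromosome 20, 32263489 to 32274210, and GFAP (ENSG00000131095.11_2) at chromosome 17, 42982376 to 42994305. HSPA5 (ENSG00000044574.7_1) lies at chromosome 9, 127997132 to 128003609. All are coordinates of whole gene loci in hg19.

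**Figure D2:**
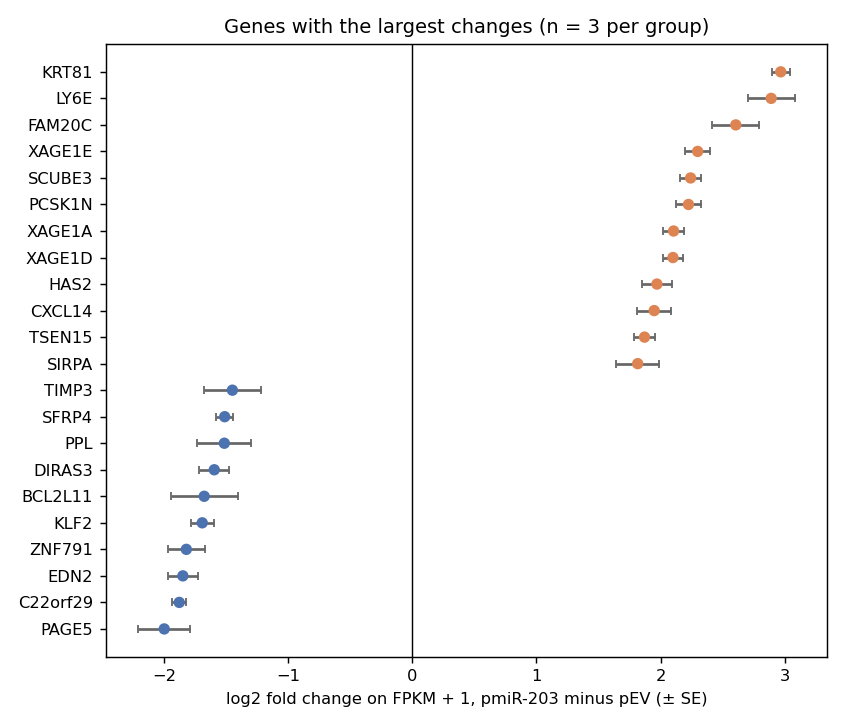
Log2 fold change on the FPKM + 1 scale (x axis, bars are the SE, n = 3 per group) of the genes with the largest increases and decreases; 2 genes on the Y chromosome are left out. KRT81 lies highest at 2.97, and SIRPA has the smallest increase at 1.82.

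The second question was which groups of genes moved together, over the 30 lists with enough members. Counts of called members are to be read against all 12287 genes tested, of which 2534 were called higher and 1061 lower. Camera called 10 of the 30 lists, 4 higher and 6 lower than other genes. With an estimated inter-gene correlation, 1 list stayed past the threshold, the G1/S and DNA replication list. For the DNA damage, Wnt and cholesterol lists the estimate was -0.002, -0.045 and 0.008, below the preset 0.01. A higher correlation among members therefore does not account for the loss of those calls. The estimate lay above 0.01 in the other lists that lost their call.

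Genes of the G1/S transition and DNA replication were higher in pmiR-203, with 36 of 38 tested members called higher and 0 lower (37 and 0 adjusted over the list alone) and a median log2 fold change of 1.03. Besides E2F1, the replicative helicase subunits MCM4 and MCM6 rose 2.59-fold and 2.92-fold. RRM2, a subunit of ribonucleotide reductase, rose from 3.56 ± 0.156 to 9.29 ± 0.115 FPKM. The list median was 1.07, 1.01 and 1.10 against pEV 1, 2 and 3 taken singly. Camera gave an adjusted p of 1.16e-17, and of 0.0141 with an estimated correlation.

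Genes of G2/M and mitosis rose as well, with 32 of 40 members called higher and 0 lower (38 and 0 adjusted over the list alone) and a median of 0.60. The motor proteins KIF4A and KIF20A rose 1.79-fold and 1.68-fold, NDC80, a kinetochore protein, 2.12-fold, and CCNB1 (cyclin B1) from 25.4 ± 1.33 to 44.3 ± 0.605 FPKM. KIF4A lies in a stretch of chromosome X, chosen after the data were seen, in which 17 of the 23 genes left out of the choice lay above the median of all genes. Camera's adjusted p was 2.28e-11, and 0.254 with an estimated correlation. In the DNA damage response and repair list, 19 of 31 members were higher and 1 lower (22 and 2 adjusted over the list alone). FANCI, PRKDC, EXO1 and BRCA1, all repair proteins, rose 2.16-fold, 1.69-fold, 3.05-fold and 2.82-fold. The adjusted p was 0.000123, and 0.113 with an estimated correlation.

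**Figure D3:**
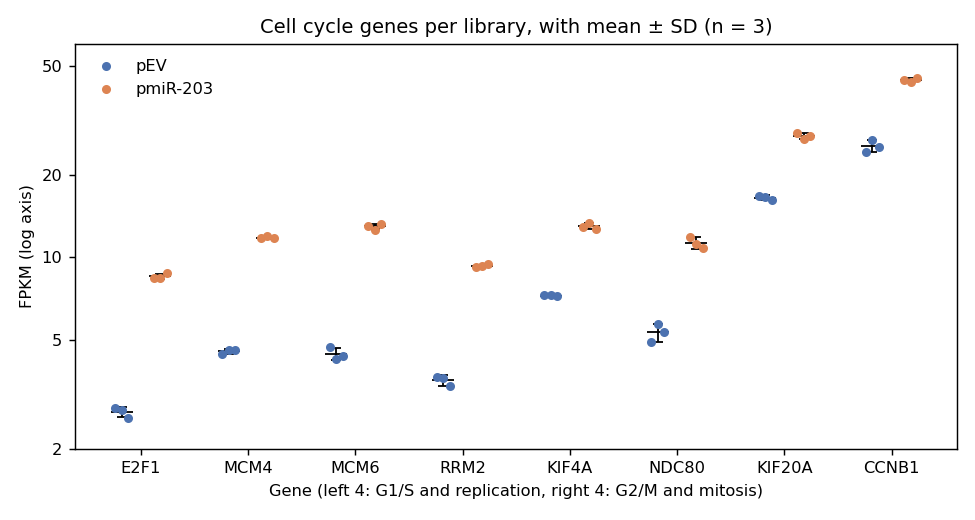
FPKM (log axis) of 4 named genes of the G1/S list and 4 of the G2/M list in each library (points), with the mean and SD of each group (black, n = 3). All pmiR-203 points of these 8 genes lie above all pEV points.

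Replication-dependent histones were lower on balance, with 4 of 14 members lower and 2 higher (4 and 2 adjusted over the list alone). This list also served to watch RNA quality. The labels do not say whether mRNA was selected, so how fully these transcripts were captured is not known. HIST2H2BE, HIST1H1C and HIST1H2AC were 2.69-fold, 1.76-fold and 1.62-fold lower, while HIST2H2AC was 2.78-fold higher. Camera's adjusted p was 0.0358, 0.344 with an estimated correlation, 0.0789 after GC correction (0.0985 also without pEV 3), 0.0682 after median-of-ratios scaling, 0.0533 with no filter on low values and 0.0666 over genes with a mean of at least 1 FPKM. HIST1H2AC lost its call when any 1 of the pmiR-203 libraries was left out (adjusted p 0.0532 to 0.0544).

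Among p53 targets, 6 of 27 were higher and 8 lower (7 and 9 adjusted over the list alone), and 3 were higher and 7 lower without pEV 3. The cell cycle inhibitor CDKN1A was 1.85-fold lower, SESN2 1.77-fold lower and BBC3, which encodes the death-promoting protein PUMA, 2.95-fold lower, while BAX, a pore-forming death effector, was 1.67-fold higher. Camera did not call this list (adjusted p = 0.172), and its median was 0.04 (mean -0.08), with a camera direction of lower. Of apoptosis regulators, 3 of 27 were higher and 5 lower (3 and 5 adjusted over the list alone). They included BIRC5 (survivin, 1.92-fold higher), BID (1.74-fold higher), BAX and BBC3. That list was not called (adjusted p = 0.387), and its median was 0.05 against a mean of -0.08.

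Genes of the unfolded protein response were lower, with 12 of 25 members lower and 4 higher (12 and 6 adjusted over the list alone) and a median of -0.33. Besides HSPA5, the stress-induced transcription factor DDIT3 was 1.89-fold lower, PPP1R15A 2.35-fold lower and SESN2 1.77-fold lower. The adjusted p was 0.00235, and 0.271 with an estimated correlation. Targets of YAP and TEAD were lower in 10 of 21 members and higher in 4 (12 and 4 adjusted over the list alone), with a median of -0.28. NT5E, LATS2 and NUAK2 were 1.94-fold, 1.70-fold and 1.88-fold lower, but ANKRD1, a well-known YAP target, rose from 1.62 ± 0.422 to 6.36 ± 0.201 FPKM. Camera's adjusted p was 0.000827, and 0.217 with an estimated correlation.

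In glycolysis, 3 of 18 members were lower and 2 higher (3 and 2 adjusted over the list alone), and 5 were lower and 3 higher without pEV 3. The glucose transporter SLC2A1 fell from 213 ± 19.4 to 88.9 ± 0.138 FPKM, hexokinase HK2 was 1.70-fold lower and GPI 1.56-fold lower, whereas PGK1, in the same stretch of chromosome X as KIF4A, was 1.79-fold higher. The adjusted p was 0.0358, 0.526 with an estimated correlation, 0.0846 without pEV 1, 0.0789 after GC correction, and 0.0589 and 0.330 under median-of-ratios and quantile scaling. In cholesterol biosynthesis, 6 of 26 members were lower and 3 higher (6 and 3 adjusted over the list alone), among them the desaturase SCD (1.48-fold lower), LSS (1.47-fold lower) and FDPS (1.38-fold higher). Camera's adjusted p was 0.0203, 0.254 with an estimated correlation and 0.0585 without pEV 2. The call of LSS was lost without pmiR-203 1 (adjusted p = 0.0656) and 3 (0.0631).

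Hypoxia targets were lower in 8 of 25 members and higher in 7 (9 and 8 adjusted over the list alone). SLC2A3 and ADM, a vasodilator peptide, were 1.89-fold and 2.11-fold lower, and the carbonic anhydrase CA12 was 1.62-fold higher. The list was not called (adjusted p = 0.0707), and it was called lower without pEV 3 (adjusted p = 0.0219, and 0.0176 with GC correction). In oxidative phosphorylation, 5 of 33 members were higher and 0 lower (2 and 0 adjusted over the list alone), with NDUFS1 of complex I at 1.44-fold, NDUFB3 at 1.52-fold and UQCRQ at 1.53-fold. That list was not called (adjusted p = 0.0977), was called higher without pEV 2 (0.0472) and after quantile normalization (0.0226). The calls of NDUFB3 and UQCRQ were lost without any 1 of the pmiR-203 libraries (adjusted p 0.0769 to 0.125), that of UQCRQ also without pEV 2 (0.0602) and after median-of-ratios scaling (0.0614), and that of NDUFS1 without pmiR-203 1 (0.0503).

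Of the mitochondrially encoded mRNAs, 1 of 13 was called (0 adjusted over the list alone), and 5 of 13 were called higher without pEV 3. MT-CO1 went from 2439 ± 190.2 to 2869 ± 22.9 FPKM and MT-ATP6 from 351 ± 48.3 to 439 ± 7.44 FPKM, the latter with an adjusted p of 0.0598 that passed without pEV 1 (0.0218), without pEV 3 (0.0282), after quantile normalization (0.0482) and after GC correction (0.0362). MT-CO1 lost its call under both other scalings (adjusted p = 0.188 and 0.463), without pEV 2 (0.0512) and without each pmiR-203 library (0.132 to 0.148). The list was not called by camera (adjusted p = 0.172) and was called higher without pEV 3 (0.0184, and 0.0202 with GC correction). Cytosolic ribosomal proteins hardly differed, with 3 of 39 members higher and 1 lower (1 and 0 adjusted over the list alone). RPL38, RPS14 and RPL6 were 1.35-fold, 1.22-fold and 1.15-fold higher, and RPLP1 1.18-fold lower. That list was not called (adjusted p = 0.642), its camera direction was lower while its median was 0.05, and quantile normalization turned it higher (adjusted p = 0.0367). RPL6 and RPLP1 lost their calls without pEV 2, without pEV 3 and without each pmiR-203 library (adjusted p 0.0515 to 0.177), and RPS14 without each pmiR-203 library (0.0842 to 0.0931). Under median-of-ratios scaling the calls of RPL6 and RPS14 were lost (0.360 and 0.0852), under quantile normalization that of RPLP1 (0.260), and that of RPL6 also after GC correction without pEV 3 (0.0774) and against pEV 2 alone (0.0846).

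The fourth list called higher was that of Wnt pathway targets, with 4 of 11 members higher and 0 lower (6 and 0 adjusted over the list alone) and a median of 0.41. CCND1 (cyclin D1) rose from 16.9 ± 1.52 to 46.9 ± 1.16 FPKM, LEF1 2.32-fold, TNFRSF19 1.62-fold and AXIN2 1.91-fold. The adjusted p was 0.0358, 0.271 with an estimated correlation, 0.0585 without pEV 2, 0.0627 without pmiR-203 3 and 0.0654 over genes with a mean of at least 1 FPKM. Notch pathway genes were called lower in 3 of 14 and higher in 1 (3 and 3 adjusted over the list alone). The ligand JAG1, the receptor NOTCH3 and the effector HEY1 were 1.87-fold, 2.02-fold and 2.23-fold lower, and the ligand DLL1 was 3.38-fold higher. The list was not called (adjusted p = 0.172), and HEY1 lost its call without pmiR-203 1 (0.0526) and 3 (0.0555).

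For MAPK feedback and immediate early genes, 10 of 24 members were higher and 3 lower (10 and 3 adjusted over the list alone), with ETV5 2.17-fold higher, EGR2 2.32-fold lower and JUNB, an AP-1 subunit, 2.69-fold lower. Camera did not call this list (adjusted p = 0.230). Among targets of TGF-beta and SMAD proteins, 5 of 20 were higher and 6 lower (6 and 8 adjusted over the list alone). ID3, an inhibitor of helix-loop-helix factors, rose from 6.96 ± 0.436 to 23.6 ± 0.904 FPKM and TGFBI 1.73-fold, against the fall of JUNB. That list was not called (adjusted p = 0.0977) and was called lower after GC correction without pEV 3 (0.0202).

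Mesenchymal genes went both ways, with 5 of 28 higher and 6 lower (7 and 7 adjusted over the list alone). Fibronectin (FN1) rose 1.63-fold and the transcription factor TWIST1 was 1.59-fold lower. Epithelial genes were lower in 4 of 11 members and higher in 1 (4 and 1 adjusted over the list alone). KRT19 rose from 0.290 ± 0.127 to 1.43 ± 0.135 FPKM, and CDH3 (P-cadherin), CLDN1 and KRT8 were 1.87-fold, 1.65-fold and 1.45-fold lower. CLDN1 and KRT8 lost their calls without any 1 of the pmiR-203 libraries (adjusted p 0.0569 to 0.106), and KRT8 also without pEV 2 (0.0663). The adjusted p of the lists was 0.151 and 0.0684, and the epithelial list was called lower without pEV 3 (0.0253, and 0.0219 with GC correction) and over genes with a mean of at least 1 FPKM (0.0200). Of collagens and extracellular matrix genes, 8 of 29 were higher and 8 lower (10 and 8 adjusted over the list alone). COL5A1 and POSTN (periostin) rose 2.83-fold and 2.63-fold, THBS2 1.62-fold, and FBN1 (fibrillin) was 1.69-fold lower. The list was not called (adjusted p = 0.148) and was called lower without pEV 2 (0.0497). Its median was -0.03, -0.03 and -0.18 against pEV 1, 2 and 3, where pEV 3 held the collagen COL3A1 at 20.6 FPKM against at most 0.146 FPKM in the other libraries.

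Interferon-stimulated genes were higher in 17 of 52 members and lower in 3 (17 and 3 adjusted over the list alone), with 16 higher and 5 lower without pEV 3. PARP14, PARP9 and TRIM14 were 1.54-fold, 1.43-fold and 1.47-fold higher, while IFI6, the most significant member, fell from 260 ± 36.3 to 133 ± 2.06 FPKM. In MHC class I antigen presentation, 4 of 17 were higher and 3 lower (5 and 5 adjusted over the list alone). HLA-E and HLA-B were 1.52-fold and 1.60-fold lower, and the trimming peptidases ERAP2 and ERAP1 were 3.84-fold and 1.65-fold higher. ERAP1 lost its call without pmiR-203 1 (adjusted p = 0.0516). Of inflammatory cytokines and NF-kB targets, 3 of 18 were higher and 3 lower (3 and 3 adjusted over the list alone), with IER3 and CXCL8 (interleukin 8) 1.91-fold and 2.44-fold higher and ICAM1 and RELB 2.03-fold and 1.77-fold lower. RELB lost its call after GC correction without pEV 3 (adjusted p = 0.0997). None of these 3 lists was called by camera (adjusted p = 0.321, 0.172 and 0.128).

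Neural and glioma stem cell markers were higher in 10 of 20 members and lower in 1 (10 and 1 adjusted over the list alone), with a median of 0.43. SOX9 rose from 44.1 ± 2.56 to 83.8 ± 0.847 FPKM, FABP7 2.30-fold and ALDH1A3 1.86-fold, beside ID3. As a list they were not called by camera (adjusted p = 0.0580) and were called higher without pEV 1 (0.0341), under both other scalings (0.0436 and 0.00294) and over genes with a mean of at least 1 FPKM (0.0396). Among astrocyte and oligodendrocyte markers, 4 of 10 were higher and 2 lower (4 and 2 adjusted over the list alone). Besides GFAP and FABP7, CNP rose 2.04-fold, and CLU (clusterin) was 2.27-fold lower. That list was not called (adjusted p = 0.782), and its median of -0.20 (mean 0.13) turned to 0.36 without pEV 3. Of neuronal markers, 0 of 11 were higher and 1 lower, ELAVL3 at 1.99-fold, with the same counts adjusted over the list alone, and MAP2 stood at 2.99 ± 0.327 and 3.59 ± 0.876 FPKM (adjusted p = 0.402). The list was not called (adjusted p = 0.217).

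Markers of blood cells were called lower in pmiR-203 as a list (adjusted p = 0.0431, 0.545 with an estimated correlation) although 0 of 8 tested members passed, also when adjusted over the list alone. The median was 0.07 and -0.14 against pEV 1 and 2 and -4.31 against pEV 3, and the call was lost without pEV 3 (adjusted p = 0.156), without pmiR-203 2 and 3 (0.0530 and 0.0589), under both other scalings (0.163 and 0.109), after GC correction (0.0789) and over genes with a mean of at least 1 FPKM (0.0633). CD14 stood at 1.43, 1.28 and 4.82 FPKM in pEV 1, 2 and 3 and at 0.619 ± 0.0662 FPKM in pmiR-203 (adjusted p = 0.0883, and 0.00731 without pEV 3), and FCER1G at 1.71 ± 2.45 and 0.228 ± 0.0809 FPKM (adjusted p = 0.346). Endothelial markers had 4 tested members and no set test, and 0 of the 4 passed, also when adjusted over the list alone. ENG stood at 3.54 ± 0.631 and 4.04 ± 0.0499 FPKM (adjusted p = 0.304, and 0.00771 after GC correction without pEV 3) and VWF at 1.74 ± 2.41 and 0.262 ± 0.0193 FPKM (adjusted p = 0.329). The median of these 4 was -0.09, 0.09 and -1.84 against pEV 1, 2 and 3.

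**Figure D4:**
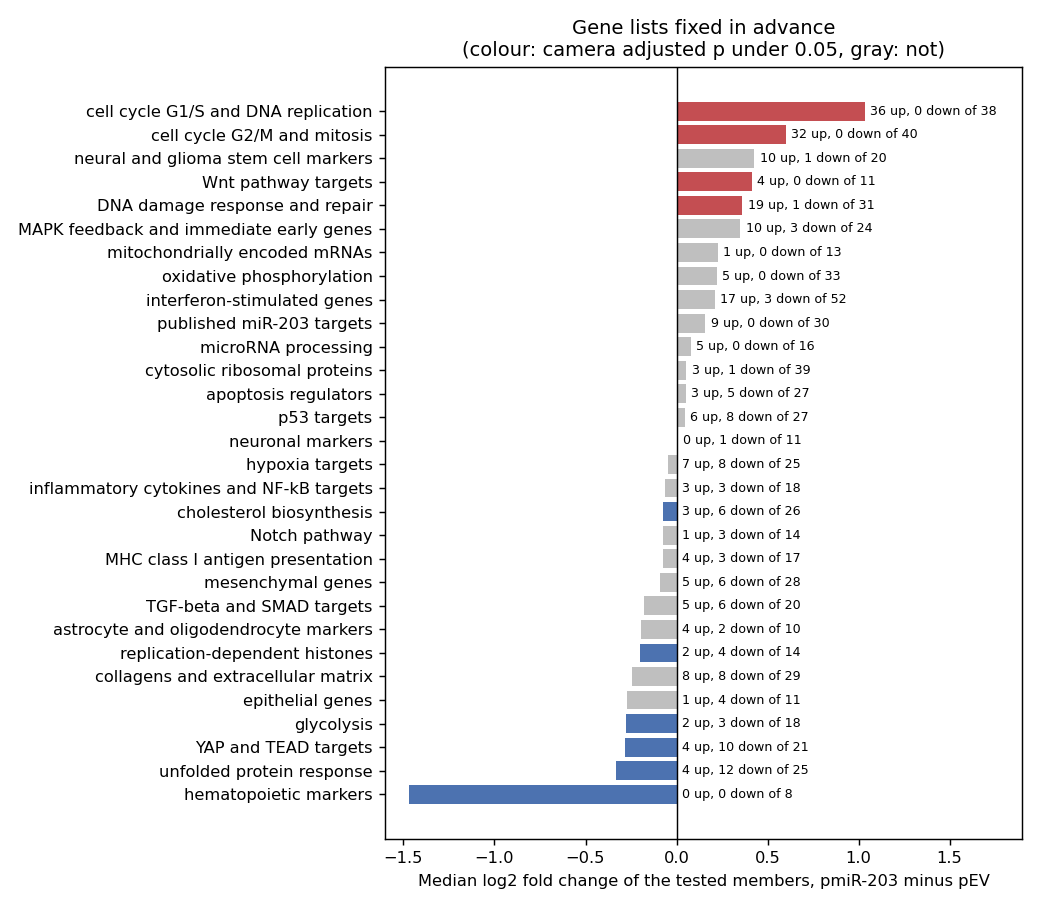
Median log2 fold change on the FPKM + 1 scale (x axis) of the tested members of each of the 30 lists, with the numbers of members called higher (up) and lower (down). Colour marks a camera adjusted p under 0.05; the G1/S list lies highest at 1.03, and the hematopoietic list lies lowest at -1.47, a value carried by pEV 3.

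The third question was whether transcripts with a site for miR-203 were lower in the cells that expressed it. Of 31 published miR-203 targets, 30 were tested, 9 were called higher and 0 lower (10 and 0 adjusted over the list alone). The 9 were BIRC5, KIF5C (1.46-fold), SKP2 (1.61-fold), RUNX2 (1.52-fold), ASAP1 (1.56-fold), MSI2 (1.63-fold), E2F3 (1.40-fold), RAPH1 (1.32-fold) and RAN (1.34-fold). Some of these, such as BIRC5 and SKP2, are also genes of proliferating cells. The list was not called (camera adjusted p = 0.642, median 0.16). In settings chosen after the data were seen, the counts were 8 higher and 2 lower after GC correction, 9 and 4 after GC correction without pEV 3, and 12 and 7 against pEV 2 alone, a fit that takes the small spread of pmiR-203 for the control. Without pEV 3, they were 10 and 1. The calls of E2F3, RAPH1, RAN and MSI2 were lost when any 1 of the pmiR-203 libraries was left out (adjusted p 0.0530 to 0.147), and those of E2F3, RAPH1 and RAN also without pEV 2 (0.0602 to 0.116) and under both other scalings (0.0840 to 0.237). After GC correction, with and without pEV 3, the calls of E2F3 and RAN were lost (0.0550 to 0.237), and that of RAN also without pEV 3 alone (0.101).

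Genes with a miR-203a-3p seed site in the 3 prime UTR (3950) and the 8142 genes without one differed little, and the test did not pass. Their median log2 fold changes were 0.11 and 0.08, an order that turned round after GC correction (0.065 and 0.095). The site coefficient after regression on UTR length and GC share was 0.0104 on the log2 scale. The exact two-sided permutation p over the 6 library coefficients was 0.3, where 0.1 is the smallest that 3 against 3 libraries can give. With 882 genes holding an 8mer site the coefficient was -0.0014, and with sites for the 5p arm (2128 genes) it was -0.0113, with an exact permutation p of 0.1 and all pmiR-203 coefficients below those of pEV. The 3p site CATTTCA ranked 11407 from the most lowered of 15923 heptamers (coefficient 0.0015), 9183 after GC correction (-0.0024) and 5247 against pEV 2 alone (-0.0091). The seed coefficient was -9e-04 against pEV 2 alone. In simulated libraries, a shift of -0.15 put into all genes with a site was returned as -0.156, against -0.00568 with no shift. This checks the computation only and does not show how small or partial an effect the test would find.

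Genes of the microRNA pathway itself were higher in 5 of 16 members and lower in 0 (5 and 0 adjusted over the list alone). Of all 12287 genes tested, 2534 were called higher, and the list median of 0.079 lay below the 0.09 of all genes. DGCR8 and DROSHA, the subunits of the nuclear processing complex, were 1.74-fold and 1.43-fold higher, and the export receptor XPO5 and the helicase MOV10 1.40-fold and 1.32-fold. Camera did not call this list (adjusted p = 0.386). MOV10 lost its call without pEV 2 and pEV 3 (adjusted p = 0.0523 and 0.0510), without each pmiR-203 library (0.0548 to 0.0822) and under both other scalings (0.0888 and 0.0717).

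At the level of transcripts, isoforms changed in genes that did not pass the test themselves. HNRNPUL1-010 went from 0.0143 ± 0.0113 to 34.2 ± 0.677 FPKM, while HNRNPUL1-011 of the same RNA-binding protein gene fell from 33.3 ± 5.27 to 1.82 ± 0.112 FPKM, and the gene itself had a log2 fold change of -0.185 and an adjusted p of 0.138. BLOC1S6-004 rose from 0.101 ± 0.0169 to 28.1 ± 0.927 FPKM and HNRNPC-006 from 0.0367 ± 0.0635 to 11.0 ± 1.03 FPKM. FGFR1-011, of a fibroblast growth factor receptor, and CCHCR1-011 were listed at 0 in all 3 pEV libraries and stood at 15.1 ± 1.71 and 7.03 ± 0.356 FPKM in pmiR-203, with log2 fold changes of -0.32 for the gene FGFR1 and 0.29 for CCHCR1 (adjusted p = 0.126 and 0.178). An isoform of IGF2BP3 (ENST00000619562.4_1) fell from 7.51 ± 0.638 to 0.198 ± 0.0418 FPKM, C1QTNF1-002 from 18.6 ± 3.34 to 0.824 ± 0.153 FPKM, DCAF1-202 from 3.37 ± 0.278 to 0.00713 ± 0.00934 FPKM, and RIC8A-001 from 9.32 ± 0.968 to 0.899 ± 0.224 FPKM. Adjusted p-values of these 10 transcripts ran from 0.000168 to 0.00441.

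Of 28450 transcripts tested, 665 passed (450 higher, 215 lower). The gene passed too for 543 of them, in the same direction for 530, and 115 belonged to a tested gene that did not pass. In 21 genes, at least 1 transcript was higher and another lower. The number of calls was 1851 without pEV 1, 208 without pEV 2, 410 without pEV 3, and 114, 142 and 128 without pmiR-203 1, 2 and 3. Isoforms of a gene share exons, so FPKM of a transcript rests on how shared reads were divided, and a single isoform value is uncertain.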

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

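The GC correction, the library weights, the fit without pEV 3 after GC correction and the fit against pEV 2 alone were chosen after the data were seen. All other settings were fixed before. The number of genes past the threshold in limma was 3595, and 2150 with the replicate number as a block (4583 at an unadjusted p under 0.05). It lay between 1710 and 5409 with 1 library left out, and 1170 genes also had a fold of at least 1.5 on the FPKM + 1 scale. The number of transcripts was 665, and 0 with the block (3952 at an unadjusted p under 0.05, against 5200 without it). It lay between 114 and 1851 with 1 library left out and was 1686 with library weights. The residual degrees of freedom are fewer in the block and left-out fits. That does not account for the rise to 5409 genes and 1851 transcripts, which came without pEV 1. The library weight of pEV 1 was 0.1, against 0.92 to 2.32 for the other libraries. Other causes were not tested. Deviations of same-numbered libraries correlated at -0.013, -0.027 and 0.015, so the numbers do not pair the libraries, and pEV 1 and 2 did not correlate best with the library of their own number. Of the 30 lists, 10 passed with a preset correlation, 1 with an estimated correlation and 16 in fry, which asks whether the members move and not whether they differ from other genes. Cytosolic ribosomal proteins turned from lower to higher than other genes after quantile normalization (median 0.116, adjusted p = 0.0367), and the cause was not tested. The seed coefficient of 0.0104 became -9e-04 against pEV 2 alone, -0.0014 with 8mer sites only, -0.0113 for the 5p arm and 0.0432 with no correction for UTR length and GC share. Over all settings, single lists kept their direction and side of the threshold in 437 comparisons with the reported result, lost a call in 33, gained one in 28, turned direction with no call on either side in 11 and turned direction with a call in 1. Named genes did so in 1867 comparisons, lost a call in 94, gained one in 11 and turned direction with no call in 1. For named transcripts these numbers were 120, 10, 0 and 0, where the 10 were all under the block. The count alternatives were not run, since the values are not counts. Depth was estimated lowest for pEV 3, at 11600000 mapped fragments, but that estimate rested on 3 values at 1 fragment. If it holds, low transcripts are the least certain there.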

Other observations

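Gene families were grouped by symbol after the data were seen, and 13 of 15 had enough tested members. Over all 12287 genes tested, 2534 were called higher and 1061 lower. Proteasome subunits were higher in 12 of 37 and lower in 0, with a median log2 fold change of 0.27. PSMA7 rose from 48.8 ± 1.84 to 73.5 ± 2.92 FPKM and PSMD4 from 19.5 ± 0.401 to 29.2 ± 1.51 FPKM (mean ± SD, n = 3). Mitochondrial ribosomal proteins were higher in 24 of 78 and lower in 2, with MRPL58 and MRPS18A both at 1.78-fold. Protocadherins were higher in 14 of 31 and lower in 1, among them PCDHB11 at 7.37-fold and PCDHB10 at 5.14-fold, whose clustered copies share sequence and are uncertain. Camera gave these 3 families adjusted p-values of 0.0376, 0.0394 and 0.0394, and 0.742, 0.742 and 0.623 with an estimated correlation. Their medians stayed above 0 under both other scalings.

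Other families were not called as a whole. HOX genes were higher in 8 of 26 and lower in 2, with HOXB13 at 2.76-fold and HOXB9 at 1.84-fold (adjusted p of the family = 0.673). The family median of 0.07 turned to -0.02 and -0.05 under the other scalings. Those scalings also lowered the median of all genes, from 0.09 to -0.007 and 0.005, so the turn is not particular to HOX genes. Among heat shock proteins, 13 of 59 were lower and 5 higher. HSPA1A and HSPA1B, near-identical copies and so uncertain, were 1.86-fold and 1.68-fold lower, and HSP90AA1 was 1.34-fold higher (adjusted p of the family = 0.136). Keratins went both ways, with KRT81 and KRT86 8.28-fold and 3.42-fold higher and KRT16 4.26-fold lower. The 5p site GAACCAC ranked 111 from the most lowered of 15923 heptamers, 190 after GC correction and 370 against pEV 2 alone, with a coefficient of -0.0367.

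All tests of the 3 patterns below were chosen after the data were seen. Library pEV 3 held transcripts of fat, blood and connective tissue, such as HBA1 at 482 FPKM, FABP4 at 107 FPKM and COL3A1 at 20.6 FPKM, against at most 2.27, 1.13 and 0.146 FPKM in the other 5 libraries. Of 35 blood and endothelial markers listed before the data were examined, 17 were measured. Of these, 7 lay over 4-fold above every other library in pEV 3 and 0 did so in any other library, so RNA of another tissue is a candidate source. Rows needed a group mean of at least 0.5 FPKM, so an excess in pEV 3 alone could bring a marker among those measured. HLA-DRA, for example, stood at 25.72 FPKM in pEV 3 and at most 0.226 FPKM elsewhere. The 7 of 17 is thus not a share of all listed markers. In lists written after the excess was seen, 15 of 15 fat cell genes, 3 of 3 red blood cell genes, 6 of 6 macrophage genes and 11 of 11 connective tissue genes were highest in pEV 3, with median excesses of 4.46, 7.20, 3.45 and 3.55 on the log2 scale. Differentiation of the cultured cells into fat cells does not account for the red blood cell transcripts (7.203), and the empty vector does not account for an excess that pEV 1 and 2 lack (0.025 at most over pmiR-203). Of the fat cell and red blood cell genes, 4 and 3 reached 1 FPKM in another library too, and where the RNA came from was not tested.

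Genes of G1/S and DNA replication were higher in pmiR-203 with a list median of 1.03. The GC trend of pEV 1 does not account for this, since the median was 1.068 after GC correction. Neither do the fat, blood and connective tissue transcripts of pEV 3, whatever their source, since the median was 1.011 without that library. A difference in growth state between the cultures at harvest stays open, because it cannot be told apart from the group in this design and the G2/M list was higher too (0.6). An effect of miR-203 or of the history of this 1 line stays open as well and was not tested.

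Stretches were picked on every other gene. Medians of 20-gene windows had to lie at least 0.3 (log2) from that of all genes used, against each of pEV 1, 2 and 3. A stretch of chromosome X from 69.5 to 100.3 Mb (hg19) was picked in this way and examined on the 23 genes left out. Their median log2 fold change exceeded that of all genes by 0.44, and a share of 0.00163 of 6127 circular shifts of the gene order gave a difference as large. The excess was 0.338 after GC correction, so the GC trend of pEV 1 does not account for all of it. Against pEV 2 alone the excess was 0.293. An excess against pEV 2 was a condition of the choice, so this value cannot exclude faults of pEV 1 and 3. A copy number difference between the lines may be the cause, but 73.9% of the genes left out lay above the median of all genes, between the bounds set for and against it. A stretch of 17q had been noticed over all genes and was not picked by this procedure, and the pattern was then limited to chromosome X.

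The same procedure picked 2 stretches of lower genes, on chromosome 1 from 2.5 to 10.4 Mb and on chromosome 13 from 96.3 to 115.1 Mb (share of shifts 0.01273 and 0.0772). Run on 1 contrast at a time, the procedure picked 9 to 20 stretches per direction between pEV 1 and another control, and 0 between pEV 2 and 3. With pmiR-203 against pEV 1, 2 and 3 singly, it picked 21, 7 and 5 stretches of higher genes. Stretches of lower genes numbered 25, 3 and 3. These counts cannot be set against the 1 higher and 2 lower stretches, which had to pass against all 3 pEV libraries at once.

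With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split was the only 1 of the 10 to give 3595 genes and 665 transcripts, and the highest of the other splits gave 1 gene and 21 transcripts. Every other split mixes both lines within its groups, so a difference between the lines adds to the spread and lowers these counts. The other splits therefore do not measure how many calls are false. For lists, 3 of the 10 splits gave as many as the real 10, with a highest of 11. For the size of the seed coefficient, 3 of the 10 gave as much as 0.0104, with a highest of 0.0116.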
